A study of Drosophila melanogaster with 6 samples.

How the data were processed

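Polyadenylated RNA of whole Drosophila melanogaster embryos at about stage 14 was sequenced in 6 libraries, 3 from wild-type embryos and 3 from embryos mutant for spo. RNA was purified on silica columns and made into libraries with a polyA-selecting kit, per the labels' protocols. The labels give each library its genotype, stage and replicate number. They do not say how embryos were collected or how mutant embryos were picked, so p-values measure the spread between these libraries.

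The authors deposited 1 table of TPM (reads divided by gene length and scaled to a fixed sum per library) for 15135 features in 6 libraries. A second deposited table holds the authors' log2 fold change, mean log2 CPM, likelihood ratio score, p-value and false discovery rate per feature, with a positive fold change where the spo libraries have the higher TPM. The submitters' processing notes name FastQC 0.11.2, STAR 2.5.3a, featureCounts, Subread, edgeR and the dm6 build. The annotation release, the strand setting and the treatment of reads shared by overlapping genes are not given in the sources used here. TPM is relative: a large rise of some transcripts lowers the value of all others in the same library.

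Depth was worked out from the TPM table. A feature's TPM in a library is a whole number of reads times a step that depends on its length and on the library. With a tolerance of 0.0001, reads came out whole for all 15135 features, and for 14156 of the 14960 features with an annotated length (94.6%) the annotated exon length alone gave whole reads. The rebuilt totals were 58810999, 55722310 and 73952229 reads in wild-type replicates 1, 2 and 3 and 50381973, 62519988 and 72874514 in spo replicates 1, 2 and 3. Mean log2 CPM from the rebuilt reads differed from that of the authors' deposited table by a median of -0.0076 with an SD of 0.129 across genes. At this depth, 1 read in a gene of 1 kb is worth 0.0315 to 0.0460 TPM. Groups of features with equal values in every library, 73 groups with 151 features of at least 1 TPM, share their reads. Genes that overlap may not be told apart. Overlaps were taken from gene spans alone, without comparing exons or strand.

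The design, fixed before the data were examined, named a count test for count tables and limma on log2(TPM + 1) for files without counts. The deposited values are TPM, so limma 3.58.1 with an intensity trend was fitted in R 4.3.3 to log2(TPM + 1) with genotype as the 1 term and a pseudocount of 1. The planned filter is made for counts and was not run on the rebuilt reads. In its place, features with at least 1 TPM in at least 3 libraries were tested, a choice made after the files were seen, which left 10019 features. Differences are spo minus wild type on the log2(TPM + 1) scale, which understates the change of low genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Folds are ratios of mean TPM. The spo gene lies under the filter and was fitted together with all 15135 features.

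The text names spo and rols, up to 8 members of the ecdysone response and myoblast fusion lists and up to 4 of every other list with the smallest p past the threshold. Over all genes it names the 10 higher and 10 lower with the largest log2 change among those past the threshold with a mean log2 CPM of at least 2 and replicate ranges that do not overlap. Features with equal values count as 1. Under the same rule, list members that did not pass may be named with their values as non-changes. Genes of the closing tests lie partly outside this rule, and those chosen after their values were seen are given there. The 28 gene lists were also fixed before the data were examined. Of their 482 written members, 16 had no match among the features. Lists were tested with camera (preset correlation 0.01, and with a correlation estimated per list) and with fry, both in limma. The list of mitochondrially encoded genes had no member in the tables and is not analysed here.

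The fitting steps were tested on simulated data with library sizes and gene means of the real libraries and 200 changed genes. Of 99 tested genes changed by 0.5 on the log2 scale, 79 were recovered, and of 99 changed by 1, 97 were recovered. Of 9725 unchanged genes, 6 were called, which made 3.3% of the calls. All simulated genes had 1 spread between replicates beyond counting (dispersion 0.000501), and no library was made to differ from its group. The real fit called 6185 genes, so the 3.3% is not the error rate of the real calls.

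Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a filter of 5 CPM (on rebuilt reads) in 3 libraries, the replicate number as a block, leaving out each library in turn, a test against a log2 change of 0.5, an estimated camera correlation and lists without shared members. Division of TPM by median-of-ratios or upper-quartile factors, voom on the rebuilt reads and library quality weights were added after the data were seen. Genes were placed with Ensembl annotation release 115 (BDGP6 assembly, the coordinates of dm6), and 14960 features matched it. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used for tables and exact tests, and figures were drawn with matplotlib 3.10.9.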

Results

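The transcriptome of whole embryos at about stage 14 was measured in 3 wild-type libraries and 3 libraries of spo mutants. The spo gene (spook) encodes a cytochrome P450 of ecdysone biosynthesis, and the comparison was made to find genes downstream of the steroid hormone ecdysone. Rebuilt library totals ran from 50381973 to 73952229 reads. Pearson correlations of log2(TPM + 1) across genes were 0.995 to 0.998 within a genotype and 0.970 to 0.975 between genotypes, and the first principal component, with 87.4% of the variance, separated the genotypes.

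The spo transcript itself was scarce in both genotypes, at 0.788 ± 0.135 TPM in wild type and 0.462 ± 0.153 TPM in the mutants (SD, n = 3). All 3 mutant libraries, at 0.610, 0.470 and 0.306 TPM, lay below the 3 wild-type libraries, at 0.944, 0.726 and 0.696 TPM. These values rest on 59, 43 and 55 reads in wild type and 33, 31 and 24 in the mutants. The log2 difference was -0.29 (SE 0.09, limma adjusted p = 0.0434). Leaving out 1 library gave adjusted p from 0.0317 to 0.136, past the threshold only without spo replicate 1. The gene (FBgn0003486) lies at 3L, 5590083 to 5592571, and its span overlaps the annotated l(3)psg2, so reads of the 2 may not be told apart. The allele is not given in the sources used here, and a mutant gene may still be transcribed. Of the 4 tested ecdysone biosynthesis genes, dib rose from 11.4 ± 0.25 to 17.4 ± 1.42 TPM, sad from 2.27 ± 0.19 to 3.24 ± 0.52 TPM, and shd, the last enzyme of the pathway, fell from 27.3 ± 0.97 to 18.1 ± 1.0 TPM (camera adjusted p = 0.933 for the list). The call of sad was lost without wild-type replicate 1 (adjusted p = 0.0570), wild-type replicate 3 (0.0613) or spo replicate 3 (0.0522).

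The 10 steepest falls taken by the fixed rule included known ecdysone response genes. Hr46, a nuclear receptor of the ecdysone cascade also called Hr3, averaged 138 ± 2.71 TPM in wild type and 14.4 ± 16.7 TPM in the mutants, and the nuclear receptor Hr4 averaged 116 ± 1.78 and 11.5 ± 13.03 TPM. ImpL1, named for its induction by ecdysone, went from 144 ± 2.30 to 8.81 ± 5.58 TPM. The juvenile hormone synthesis gene jhamt went from 58.5 ± 2.36 to 5.0 ± 8.07 TPM, and tal-1A, 1 of 4 features of the tal locus for small peptides with equal values, from 256 ± 6.59 to 22.8 ± 28.9 TPM. The other steep falls were CG31300 (log2 difference -3.83), CG12912 (-3.64), CG9184 (-3.56), CG14110 (-3.56) and p24-2 (-3.17). CG12912, at 2R, 10205454 to 10234607, lies within Hr46, at 2R, 10203995 to 10237348, so its reads and those of Hr46 may not be told apart. Hr4, CG9184 and p24-2 also overlap another annotated gene.

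The large SDs of these falls came from spo replicate 2. Hr46 stood at 4.73, 33.7 and 4.72 TPM in spo replicates 1, 2 and 3, and jhamt at 0.300, 14.3 and 0.384 TPM. Without replicate 2, the fold of wild type over spo rose from 9.57 to 29.1 for Hr46, from 10.1 to 29.4 for Hr4, from 16.4 to 25.8 for ImpL1, from 11.7 to 171 for jhamt, from 11.3 to 41.9 for tal-1A and from 7.18 to 187 for CG31300. It rose from 9.16 to 26.4 for CG12912, from 9.13 to 19.8 for CG9184 and from 8.57 to 22.4 for CG14110. For p24-2 it was 118 with and 103 without that library.

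Of 10019 genes tested, 3393 were higher and 2792 lower in the mutants (limma, adjusted p below 0.05). The split was 3126 and 3074 with median-of-ratios scaling and 3318 and 2851 with upper-quartile scaling. In the main fit, 267 higher and 262 lower genes differed by at least 1 on the log2 scale. Their total of 529 ran from 332 to 849 with other settings. Tested against a log2 change of 0.5, 870 genes were called. The authors' deposited table calls 5635 of the tested genes, of which 5461 were called here with the same sign. Counts of list members below are over all genes tested. The counts adjusted over the list alone were equal, except in 5 lists where they are given.

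**Figure D1:**
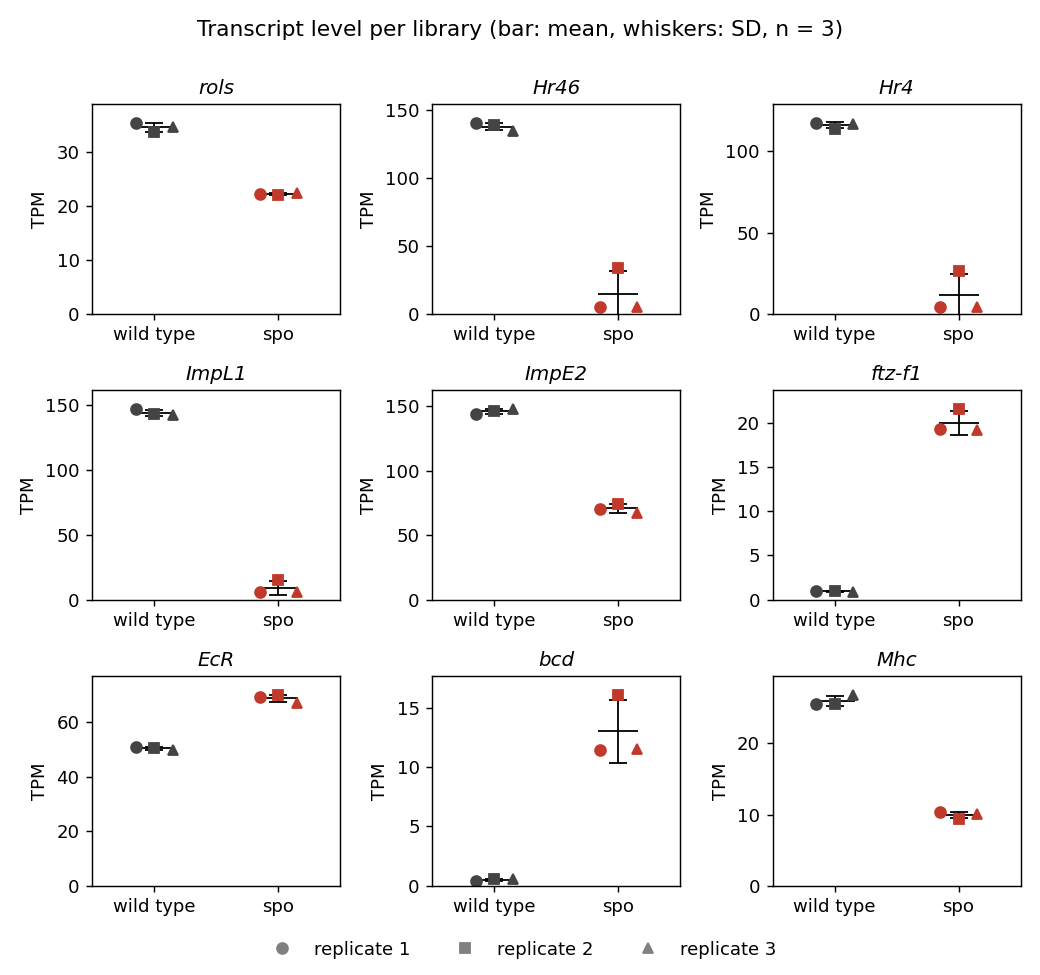
TPM (y axis, linear, from 0) of 9 genes in each library of wild type and spo. Symbols are replicates, the horizontal bar is the mean and whiskers are the SD (n = 3), stopping at the axis where the SD exceeds the mean. Hr46 stood at 33.7 TPM in spo replicate 2 and below 5 TPM in the other spo libraries, while rols lay near 22.1 TPM in all 3.

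Across the ecdysone response list, 18 of 27 tested members fell and 5 rose. The list was lower as a set (camera adjusted p = 0.00714), and with an estimated correlation the adjusted p was 0.693. ImpE2 fell from 146 ± 1.70 to 70.8 ± 3.37 TPM, ImpE1 from 62.9 ± 0.39 to 27.1 ± 3.35 TPM and ImpL2, a secreted insulin-binding protein gene, from 492 ± 11.8 to 353 ± 18.0 TPM. Eip71CD fell from 51.2 ± 1.88 to 29.0 ± 0.22 TPM, and Cyp18a1, which encodes an ecdysone-inactivating enzyme, from 2.25 ± 0.21 to 0.562 ± 0.147 TPM. In the other direction, the ecdysone receptor gene EcR rose from 50.5 ± 0.55 to 68.7 ± 1.36 TPM. The nuclear receptor gene ftz-f1 rose from 0.948 ± 0.027 to 20.0 ± 1.32 TPM (log2 difference 3.43, SE 0.06, adjusted p = 7.02e-07). ftz-f1 RNA is also supplied by the mother, and the maternal transcript bcd stood at 0.517 ± 0.082 TPM in wild type and 13.01 ± 2.63 TPM in the same spo libraries. The list members usp, Eip63E, ImpE3 and crol did not pass the threshold, with log2 differences from -0.09 to 0.13 and adjusted p from 0.118 to 0.987.

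rols (antisocial), which encodes an adaptor protein of founder myoblasts needed for fusion, fell from 34.5 ± 0.78 to 22.1 ± 0.25 TPM (log2 difference -0.62, SE 0.03, adjusted p = 7.52e-06), lower in 3 of 3 mutant libraries. The gene (FBgn0041096) spans 3L, 12008225 to 12064859, and overlaps 4 other annotated features. Of the 35 tested myoblast fusion genes, 10 rose, 10 fell and 15 did not pass, and the list did not move as a set (camera adjusted p = 0.933). By fry, which asks whether a list's own genes move, the adjusted p was 0.195 for 1 direction and 2.52e-06 for either direction, against 0.0416 and 3.17e-06 for the ecdysone response list. For either direction, the fry adjusted p was at most 0.00897 over all 27 tested lists. With 61.7% of all tested genes called, that value does not set the fusion list apart. mspo fell from 9.94 ± 0.14 to 6.38 ± 0.42 TPM, and its ratio of mean TPM, wild type over spo, equalled that of rols at 1.56. The actin regulators SCAR and Hem fell from 118 ± 0.76 to 98.1 ± 2.95 TPM and from 129 ± 2.89 to 109 ± 2.97 TPM, with beta-Spec at 446 ± 12.1 and 379 ± 3.52 TPM. Swip-1 rose from 154 ± 2.48 to 223 ± 2.24 TPM, Graf from 39.9 ± 0.41 to 52.1 ± 1.46 TPM and blow from 95.3 ± 2.13 to 114 ± 0.75 TPM. mbc, which encodes a guanine nucleotide exchange factor for Rac, had a log2 difference of 0.01 (adjusted p = 0.775).

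Sarcomere genes were lower as a set, with 15 of 26 falling and 4 rising (camera adjusted p = 0.00714, with an adjusted p of 0.513 with an estimated correlation). A difference in embryo age between the wild-type and spo pools was not separated from genotype, here, for rols or in the other lists. Adjusted over the list alone, 16 fell. Mhc, the muscle myosin heavy chain, fell from 25.9 ± 0.69 to 9.93 ± 0.44 TPM, Mlc2 from 123 ± 2.83 to 75.1 ± 1.31 TPM, wupA (troponin I) from 39.2 ± 0.86 to 22.7 ± 0.89 TPM and Argk, arginine kinase, from 446 ± 5.68 to 342 ± 1.92 TPM. Of 25 muscle identity genes 6 rose and 8 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.495). nau, the fly MyoD gene, rose from 11.4 ± 0.42 to 16.1 ± 0.22 TPM, while org-1 fell from 19.1 ± 0.78 to 14.4 ± 0.89 TPM. In the visceral muscle and heart list, 3 of 16 rose and 1 fell (0.933).

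Epidermal and tracheal lists were lower as sets. In the epidermal barrier and denticle list 13 of 18 fell and 4 rose (camera adjusted p = 0.00714, with an adjusted p of 0.257 with an estimated correlation), among them the zona pellucida domain genes mey, from 40.2 ± 0.95 to 22.1 ± 0.50 TPM, tyn, from 158 ± 2.65 to 95.4 ± 5.30 TPM, and neo, from 163 ± 4.53 to 70.5 ± 8.64 TPM. In the trachea list 12 of 24 fell and 3 rose (0.0114, with an adjusted p of 0.257 with an estimated correlation). Osi6 fell from 73.8 ± 2.22 to 13.5 ± 0.96 TPM, Osi7 from 63.7 ± 1.92 to 7.92 ± 3.02 TPM and Osi15 from 7.37 ± 0.35 to 0.859 ± 0.220 TPM. Of 18 chitin genes 11 fell and 4 rose (12 and 4 adjusted over the list alone, camera adjusted p = 0.0533, with an adjusted p of 0.513 with an estimated correlation). The chitin list passed without wild-type replicate 1 (0.0464) or 2 (0.0499), without spo replicate 3 (0.0468) and with voom (0.0427). The chitin deacetylase genes serp and verm fell from 274 ± 2.71 to 106 ± 7.76 TPM and from 539 ± 4.89 to 353 ± 8.38 TPM, Gasp fell from 79.7 ± 2.34 to 21.6 ± 2.68 TPM, and Gfat1, at the entry to chitin precursor synthesis, rose from 26.9 ± 0.26 to 48.9 ± 2.11 TPM. Cuticle protein genes went both ways, with 14 of 26 higher and 7 lower (0.388). obst-A rose from 73.0 ± 1.46 to 149 ± 6.62 TPM and Cpr76Bc from 1.44 ± 0.21 to 9.43 ± 0.83 TPM, while Cpr11A fell from 36.0 ± 0.46 to 13.9 ± 1.12 TPM.

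Of 16 neuron genes 10 fell and 2 rose (camera adjusted p = 0.0533, with an adjusted p of 0.693 with an estimated correlation). The neuron list passed without the filter (0.0225), with library weights (0.0291), with the replicate block (0.0471), and without wild-type replicate 2 (0.0499) or spo replicate 2 (0.0241). VAChT, the vesicular acetylcholine transporter, fell from 8.95 ± 0.51 to 3.64 ± 0.50 TPM and nSyb, neuronal synaptobrevin, from 8.58 ± 0.27 to 2.96 ± 0.82 TPM, while unc-13 rose from 21.3 ± 0.25 to 29.4 ± 0.28 TPM. Of 15 neuroblast genes 9 rose and 4 fell (0.320). The proneural genes sc and l(1)sc rose from 9.59 ± 0.16 to 18.3 ± 0.44 TPM and from 22.1 ± 0.65 to 34.7 ± 1.67 TPM, and insc fell from 48.6 ± 1.17 to 36.7 ± 0.77 TPM. Of 24 cell cycle genes 16 rose and 3 fell (0.00714, with an adjusted p of 0.257 with an estimated correlation). The replication licensing gene dup rose from 120 ± 1.58 to 185 ± 4.02 TPM and Mcm7 from 189 ± 1.13 to 231 ± 1.99 TPM. twe, the germ line and maternal Cdc25 phosphatase, belongs to this list and rose from 0.789 ± 0.111 to 30.1 ± 4.78 TPM. Of 15 glial genes 7 rose and 5 fell (0.933).

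The steepest rises included transcripts known to be loaded into eggs by the mother. wisp, a cytoplasmic poly(A) polymerase of egg activation, rose from 1.11 ± 0.14 to 31.8 ± 3.64 TPM, BigH1, a linker histone of the early embryo, from 2.39 ± 0.12 to 48.0 ± 7.37 TPM, and tor, the terminal receptor tyrosine kinase, from 0.482 ± 0.067 to 15.01 ± 1.90 TPM. The other steep rises were CG5568 (log2 difference 4.27), twe (4.11), Trf4-2 (3.62), CG13067 (3.50), swa (3.48), ftz-f1 (3.43) and CG17018, now called Marf1 (3.28). CG5568 and twe overlap another annotated gene. In the germ line and maternal list 11 of 16 rose and 3 fell (camera adjusted p = 0.0233, with an adjusted p of 0.572 with an estimated correlation). swa, which localizes bcd RNA in the oocyte, rose from 0.609 ± 0.094 to 17.0 ± 1.91 TPM, bcd from 0.517 ± 0.082 to 13.01 ± 2.63 TPM, spn-E from 6.57 ± 0.21 to 16.5 ± 1.17 TPM and aub from 39.6 ± 1.35 to 52.3 ± 2.01 TPM. nos had a log2 difference of -0.03 (adjusted p = 0.832) and exu of 0.18 (0.0811). In the gap and pair-rule list 8 of 21 rose and 3 fell (0.388), with slam, which acts in cellularization, at 0.444 ± 0.026 and 12.4 ± 1.49 TPM.

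**Figure D2:**
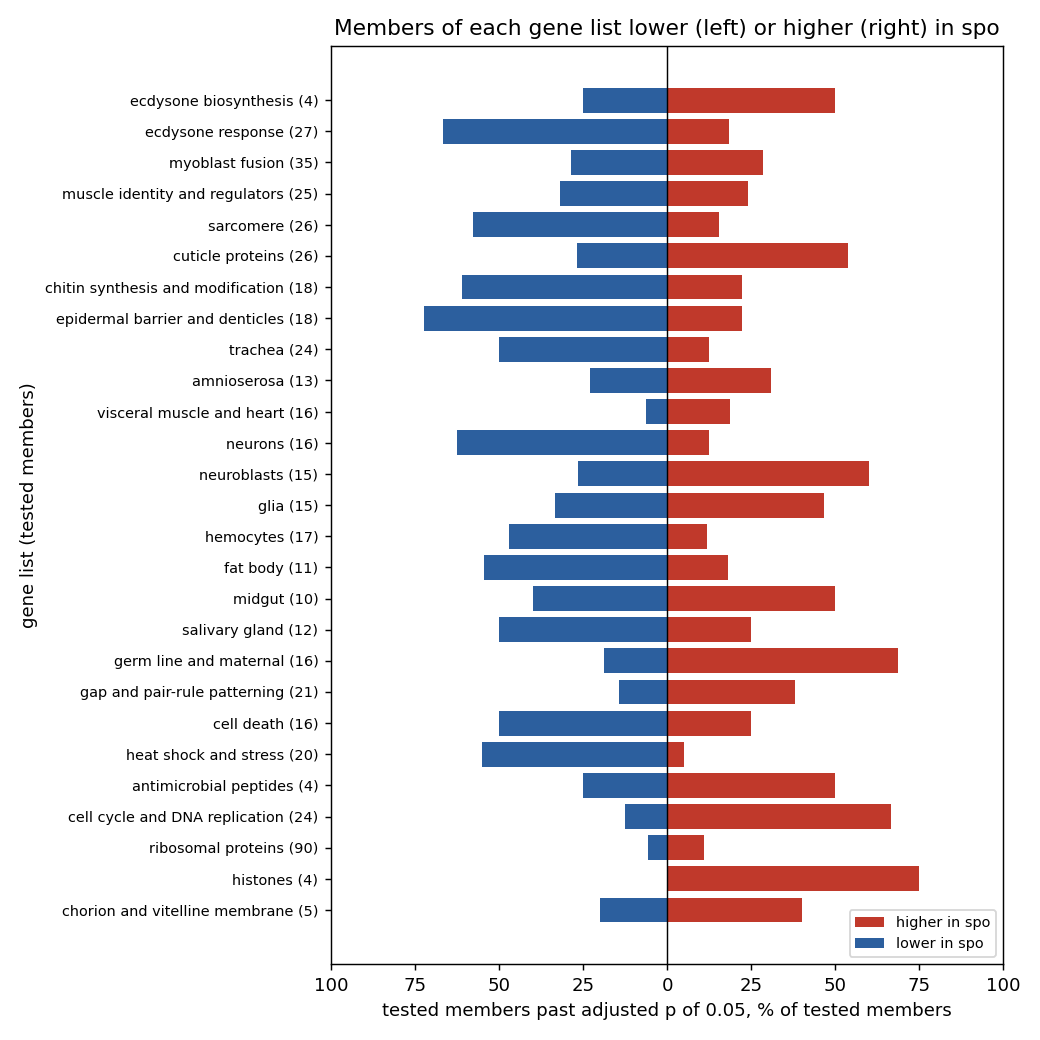
Share of the tested members of each gene list (x axis, percent) that were lower (left, blue) or higher (right, red) in spo at a limma adjusted p below 0.05 over all genes tested, with the number of tested members in parentheses. The ecdysone response list had 18 of 27 members lower and the germ line and maternal list 11 of 16 higher.

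Heat shock and stress genes were lower as a set, with 11 of 20 falling and 1 rising (camera adjusted p = 0.00714, with an adjusted p of 0.572 with an estimated correlation). Hsp70Bb, 1 of several near-identical copies, fell from 159 ± 3.95 to 51.3 ± 3.13 TPM, Hsp67Bc from 422 ± 4.18 to 286 ± 7.04 TPM and Hsp83 from 1202 ± 6.31 to 918 ± 30.0 TPM. The Hsp70 copies did not move together. In the authors' deposited table Hsp70Ba was lower (log2 fold change -1.46) and Hsp70Bc, named after its value was seen, higher (0.35, false discovery rate 1.53e-09). Hsp70Aa, Hsp70Ab and Hsp70Bbb had false discovery rates from 0.196 to 0.512 there. In the remaining lists no set passed camera. Members higher and lower numbered 2 and 8 of 17 for hemocytes (adjusted p = 0.11), 2 and 6 of 11 for fat body (0.388), 5 and 4 of 10 for midgut (0.933), 3 and 6 of 12 for salivary gland (0.439) and 4 and 8 of 16 for cell death (0.388). They numbered 4 and 3 of 13 for amnioserosa (5 and 4 adjusted over the list alone, 0.982), 2 and 1 of 4 for antimicrobial peptides (0.724) and 10 and 5 of 90 for ribosomal proteins (4 and 2 adjusted over the list alone, 0.933). They numbered 3 and 0 of 4 for histones (0.439). Of these, Ark, the apoptosome gene, fell from 66.6 ± 0.53 to 39.5 ± 2.65 TPM, Mtp of the fat body fell from 194 ± 2.91 to 114.7 ± 3.20 TPM, and the starch-digesting Mal-A1 of the midgut rose from 8.11 ± 0.73 to 19.1 ± 1.86 TPM. The chorion and vitelline membrane list (2 of 5 higher and 1 lower, 0.933) took in genes by name pattern, and its rising members were Cp1, a cysteine protease, and Cp190, an insulator protein, neither of them an eggshell gene.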

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

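The alternative scalings, voom and library weights were chosen after the data were seen. Under the 14 refits, rols kept its fall and its call, between -0.66 and -0.60. The spo gene, fitted with all features in every setting, fell in each, but its call was lost with a pseudocount of 0.1 (-0.69, adjusted p = 0.0668), with library quality weights (-0.26, 0.0657) and in 5 of 6 refits without 1 library. Over all 6 the difference ran from -0.37 to -0.21. The cause was not tested, but the gene had 24 to 59 reads per library. The 6185 changed genes became 870 when tested against a log2 change of 0.5. The 529 genes changed by at least 1 on the log2 scale became 814 with a pseudocount of 0.1, 332 with a filter of 5 CPM, which tests fewer genes, and 849 with voom on rebuilt reads, which changes the unit, offset, weights and scaling at once. The cause of the pseudocount and voom counts was not tested. Of the calls, 54.9% were higher in spo, against 50.4% with median-of-ratios factors (3126 higher, 3074 lower) and 50.1% with voom (3136 and 3119). With upper-quartile factors 53.8% were higher (3318 and 2851). Called gene lists numbered 7, and from 7 to 9 over the 14 refits. There the neuron list gained a call in 5 and the chitin list in 4. With the correlation estimated by camera, 0 of 27 lists were called and 3 had an unadjusted p below 0.05. That form also takes its degrees of freedom from the 6 libraries. The estimate lay below the preset 0.01 for the epidermal (-0.0239), trachea (-0.012) and cell cycle (-0.0105) lists, so a larger correlation does not account for their lost calls. It lay above 0.01 for the ecdysone response (0.651), heat shock (0.143), germ line (0.114) and sarcomere (0.0662) lists. Without spo replicate 2, 6469 genes were called, 5924 of them shared with the 6185. Of 1724 refits of the 124 other genes that the naming rule selects, 3 lost the call, all of sad, and 0 turned direction. Not all of these genes are named in the text, and genes named as non-changes were not among them. With the replicate number as a block, 6086 genes were called and spo and rols kept their calls. Deviations of same-numbered libraries correlated at -0.0275, 0.0450 and 0.129, so the numbers were not taken as pairs. The planned count-based alternatives (DESeq2, size factors and upper-quartile scaling in edgeR, and the count filter) were not run.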

Other observations

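The tests of germ cells, of wild-type material and of a common share were chosen after the result was seen, as were the naming of vas, pgc, Kr-h1, Oatp74D, osk, S-Lap1, CG31468, CG4367 and Ef1alpha48D, the added cutoffs of the chromosome test and the minimum of 1 TPM. A few genes were nearly silent in 1 genotype. p24-2, S-Lap1, CG4367 and CG31468 averaged 8.63, 8.15, 5.84 and 7.43 TPM in wild type and stayed below 0.1 TPM in each spo library. In the authors' deposited table, Ef1alpha48D has a likelihood ratio of 9390100 with a log2 fold change of -0.04, while its TPM ran from 13245 to 13609 over the 6 libraries.

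In the germ line and maternal list 11 of 16 genes rose in spo and 3 fell (camera adjusted p = 0.0233, with an adjusted p of 0.572 with an estimated correlation). Younger, cellularizing embryos in the pools would bring the zygotic genes of that stage. The panel of nullo, bnk, Sry-alpha, halo, Z600, ftz and prd had a median log2 difference of -0.010 (SD 0.167), although its member ftz rose (0.33, limma adjusted p = 0.000455). Outside the panel, run rose by 0.39 (limma adjusted p = 8.2e-05). The cellularization gene slam rose by 3.21 (limma adjusted p = 1.05e-06), unlike the panel but near the 3.19 of the maternal transcript bcd. Whether this slam RNA was zygotic or maternal was not tested, so slam cannot decide between younger embryos and maternal RNA. More germ cells would raise germ cell genes as much as bcd and swa, but the median log2 difference of bcd and swa exceeded that of vas, nos, pgc and aub by 3.04. Unfertilized or early arrested eggs may remain as a source: osk, bcd and swa were 1.40 times (median) higher in spo replicate 2 than in replicates 1 and 3, with a spread of 1.12-fold. That is near 1 common factor but rests on only 3 genes, so it was not decided, and slower clearance of maternal RNA in spo embryos was not tested.

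The share of the wild-type difference in spo replicate 2, counted from replicates 1 and 3, had a median of 0.170 over 52 genes at least 4-fold lower there and at 10 TPM or more in wild type, 7 of them within 0.05 of 0, and with a minimum of 1 TPM a median of 0.130 over 144 tested genes, 38 of them within 0.05 of 0 and 14 at or below 0. The 51 genes at least 4-fold higher, at 10 TPM or more in replicates 1 and 3, went both ways, with a median of -0.220 and 17 nearer to wild type. With a minimum of 1 TPM, the higher genes had a median of -0.119 over 130 tested genes, 54 of them nearer to wild type. Reads or RNA from the wild-type libraries would reach every gene, but 4 genes above 5 TPM in wild type and below 0.1 TPM in replicates 1 and 3 had a median share of 0.00039, against 0.218 for Hr46. Embryos with the wild-type profile at 1 common share would give lowered ecdysone response genes like shares, and 12 of 15 lay between 0.153 (ImpE1) and 0.302 (Oatp74D), within 2-fold of each other, with ImpL1 (0.0696, error 0.0054), ImpE2 (0.0676, error 0.0236) and Eip71CD (0.0080, error 0.0498) lower. Kr-h1 (0.240) and ImpL1 differed 3.45-fold, beyond a 2-fold gap by 7.69 errors where 3.49 were needed over 210 ordered pairs. No pair without ImpL1 passed (at most 2.69 errors where 3.46 were needed). An earlier form of the test with counting error alone gave 4.18 errors where 5 were needed. ImpL1 thus went against 1 common share for all 15 genes. Among the others, a common share was not excluded, because the test asks only for gaps beyond 2-fold. Such embryos would also raise rols in replicate 2 and move the 51 higher genes toward wild type. rols, at 34.5 TPM in wild type, stood at 22.1, 21.9 and 22.4 TPM in spo replicates 1, 2 and 3. Of the 51 higher genes, 34 had shares at or below 0. The rols values argue against 1 common share for rols. The 34 genes cannot decide it, because maternal RNA also differed between the spo libraries. The maternal transcript wisp stood at 29.5, 36.0 and 29.8 TPM in spo replicates 1, 2 and 3. More maternal RNA in replicate 2 would lower such shares at any share of wild-type embryos. How many of the 34 genes are maternal was not tested. Embryos of differing age or hormone level in replicate 2 were not tested and stay open. A difference in age between the wild-type and spo pools was not tested either. The panel of nullo and other zygotic genes asks only about cellularizing embryos, so it cannot tell a smaller lag from an effect of genotype. That question stays open for rols and for the sarcomere, epidermal, trachea, neuron and cell cycle lists.

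For genes nearly absent from 1 genotype, a strain difference on the third chromosome, which carries spo, is a candidate explanation. Of 27 genes with a 10-fold difference and a shift below 0.1 in spo replicate 2, 19 lay on chromosome 3, against 44.2% of the other tested genes (odds ratio 2.996, Fisher's exact p = 0.0102, two-sided). Not all 27 were nearly absent. The ecdysone response gene ImpL1, on 3L, averaged 8.81 TPM in spo and was among the 19. At shift cutoffs of 0.05 and 0.2 the odds ratio was 3.78 and 3.16, and with overlapping features merged it was 2.68 at 0.1, 3.53 at 0.05 and 2.92 at 0.2. The 55 genes with a larger shift had an odds ratio of 1.75 (Fisher's exact p = 0.0413), or 1.68 (0.0831) with overlaps merged, and the difference between the 2 sets was not tested. An effect of spo itself on these genes stays open, because genotype and strain background were not separated.

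Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 6185 genes by limma. The highest of the other splits gave 0, with at most 250 genes at an unadjusted p below 0.05. Each of them mixes the genotypes, so the genotype difference widens the spread within its groups. Few calls there were fixed in advance and say nothing about a batch. With 10 splits the share cannot fall below 0.05.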
